A study of Mus musculus with 18 samples.

How the data were processed

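Spleen, lung and liver came from male Swiss Albino mice aged 6 to 8 weeks, per the labels. An infected mouse received 1670 cfu of Pasteurella multocida, a Gram-negative coccobacillus that causes haemorrhagic septicaemia and pneumonia in livestock, by the intraperitoneal route in 0.1 ml. Infected tissues were taken at 6 h, a stage termed onset, or at 18 h, a stage termed late. Control mice received buffered saline in the same volume, and their tissues were taken at 18 h only, so the onset comparison also spans a difference in time after injection. Per the labels' protocols each stage had 6 mice, whose RNA was combined in 2 pools of 3 mice. The 3 tissues and 3 stages give 9 groups of 2 arrays, 18 arrays in all. The pools of one stage hold different mice, so the spread between them is biological, damped by pooling. Per the labels' protocols the RNA integrity number was above 7 and 100 ng of RNA was labelled with Cy3 for 1-colour hybridisation.

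The arrays were read by the submitters with Agilent Feature Extraction 11.5.1.1, per the submitters' processing notes and the file headers. The deposited scanner output holds, per the file headers, a processed spot intensity on a linear scale after background subtraction, a median intensity, a background median intensity, and flags for spots well above background, saturated spots and outlier spots. The headers place the probes on the mm9 build. No coordinates are given here. The authors' deposited series table holds log2 values whose scale the sources used here do not state. Set against the scanner files, each of its columns correlated at 0.9997 or 0.9999 with, or between these with, log2 intensity minus the array's 75th percentile minus the probe's median over the 18 arrays. The medians of its columns were -0.1854 and 0.0573 for spleen control 1 and 2, 0.5117 and 1.5743 for lung control, 0.5149 and 1.1085 for liver control, 0.1079 and -0.0903 for spleen onset, -0.0974 and -0.3398 for lung onset, -0.1641 and -0.2889 for liver onset, -0.0964 and 0.0811 for spleen late, -0.0776 and -0.2022 for lung late, and -0.0376 and 0.2408 for liver late. Scale, centring and direction were thereby found from the values. The small residual difference between the tables, an SD of at most 0.0320 log2, was not traced. That table served as an alternative only.

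Each array carried 62976 spots, of which 59305 were not controls and belonged to 55681 different probes. Spots of one probe were averaged. Gene names were absent from the columns of the scanner files used here, so symbols came from the platform's annotation table, updated through its gene identifiers with a gene table of assembly GRCm38.p6 where it held them. That table gave 1 symbol for 30626 probes and several for 0 probes. A further 1024 probes were named through the accession in the scanner file, and 24031 probes stayed without a name here. The named probes covered 22613 symbols.

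The main values were log2 of the processed intensity minus the 75th percentile of each array. Outlier spots were left out, and 0 spots were saturated. A probe was kept when it was well above background on both arrays of at least 1 of the 9 groups. The brightest kept probe stood for its gene, which left 17154 genes. Of these, 5271 had several kept probes, and a second probe of the same gene was called in the opposite direction for 0 genes in the spleen comparisons, 1 in lung onset, 1 in liver onset and 15 in liver late. A gene not well above background on either array of a group has only a bound there. It is given as at least so many fold, from the bright group's mean against a floor for the dim group. That floor was the mean of, per array, the higher of the lowest signal among probes well above background and the dim probe's own.

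Tests used limma 3.58.1 in R 4.3.3, with lmFit on 9 group means over all 18 arrays, which leaves 9 residual degrees of freedom, and eBayes with an intensity trend. The 9 groups share one estimate of the spread per gene because 2 arrays per group give too few degrees of freedom alone. Tests were two-sided, and the threshold was a Benjamini-Hochberg adjusted p under 0.05. Fold changes are given on the log2 scale with the standard error of the fit, and n is 2 arrays in each arm unless another n is stated. Differences of the infection response between tissues were tested with limma's F test over the 3 tissue contrasts. Where outlier spots were missing, that F test and the fits with a random block use limma's approximation for correlated contrasts. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 44 lists, and again with the correlation estimated from the residuals. Counts of list members are given as adjusted over all genes, and adjusted over the list alone where stated. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the files and drew the plots.

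Chosen before the data were examined were the comparisons, the fit, the filter, the 44 lists with at least 5 measured members required of each, the other settings to be tried and the rule for naming genes. That rule takes, for each comparison with control, the 8 largest rises and 8 largest falls among genes well above background on all 4 arrays, the 4 largest of each kind given as bounds, up to 4 called members of each list described, and a panel of 8 genes (Il1b, Il6, Tnf, Cxcl1, Cxcl10, Saa3, S100a8, Hmox1). For late against onset it takes 4 rises and 4 falls, and for the tissue differences the 6 genes per stage with the smallest F-test p that were called with opposite signs. A list is described where it passes its test or at least 1 in 3 of its measured members are called. A gene named outside the rule is said to be so.

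The signal limits precision unevenly. The 75th percentile of the processed intensity was 31.3 on the array labelled lung control 2, 42.5 on liver control 2 and 1520 on liver control 1, and 232 to 698 on the other 15. The share of spots well above background was 26.595%, 30.765% and 87.387% on those 3 arrays and 42.399% to 66.72% on the others. Liver control 1 also had 17.206% of its spots marked as outliers. The header slide numbers and scan times put the 2 spleen controls and all onset arrays on slide 1, and lung control 1, liver control 1 and all late arrays on slide 2, scanned 1 day later. Lung control 2 and liver control 2 were scanned 399 days after the first session, and their headers carry slide 1 and the positions of spleen control 2 and spleen control 1. Only spleen onset against control therefore lies within 1 slide and session.

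Tissue markers were read on every array, and 5 arrays carried those of another tissue than their label. No array was relabelled or moved. Each leading count without these 5 arrays (lung control 1 and 2, liver control 1 and 2, liver onset 2), each slide alone and the scan session as a random block were added as alternatives after seeing the data. Settings fixed in advance were normexp background correction with an offset of 50, quantile normalisation, no filter, a filter requiring signal on all 18 arrays, the mean of a gene's probes, a fit per tissue, blocks for replicate number, pool and slide, a fold threshold of 2, the authors' table, other set tests and leaving out each array. Normexp was run on the median spot intensity, since the mean was not among the columns used here.

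The code was tested on simulated data made for spleen onset against control over 17154 genes with 200 changed. The 18-array fit recovered 1.49% of genes changed by log2 1, 22.4% of those changed by 2 and 62.1% of those changed by 4, with 2 of 16934 unchanged genes called. The fit of the 6 spleen arrays recovered 47.8%, 77.6% and 95.5%, with 5 unchanged genes called. Each simulation drew its noise from the residual SD per gene of its own fit. The median of that SD was 0.61 log2 over 18 arrays and 0.159 in the spleen fit. The 18-array simulation thus gave spleen pools a wider spread than the spleen arrays show, so its recovery and false calls do not describe those arrays. Camera found the 1 shifted list of 20 genes and 0 of 100 unchanged lists in both fits. The simulated genes varied independently of each other, so this does not test list calls where genes are correlated. The simulated F test for the tissue difference at onset recovered 0% of genes changed by log2 1, 4.48% of those changed by 2 and 33.3% of those changed by 4, with 1 unchanged gene called.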

Results

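Expression was measured on 18 arrays, 2 pools of 3 mice for each of 9 groups, to find which genes of the mouse change in spleen, lung and liver at the onset of disease (6 h) and at a late stage (18 h) after intraperitoneal infection with Pasteurella multocida. Between 42.399% and 66.72% of spots lay well above background on 15 arrays. The exceptions were the arrays labelled lung control 2 (26.595%), liver control 2 (30.765%) and liver control 1 (87.387%). The number of arrays, 2 per group, limits the precision of every value below.

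Marker genes of each tissue were read first, as levels in log2 relative to the array's 75th percentile. Alb, serum albumin made by hepatocytes, stood at 9.59 on liver onset 1 and at 9.58 and 9.62 on the liver late arrays. It stood at 10.11 on the array labelled lung control 1 and at 1.37 on the array labelled liver control 1. Sftpc, surfactant protein C of alveolar epithelial cells, stood at 8.60 and 8.46 on the lung onset arrays, at 7.65 on the array labelled liver control 1 and at 8.51 on the array labelled liver onset 2, against -2.31 on the array labelled lung control 1. The arrays labelled lung control 2 and liver control 2 carried Cd79a, a part of the B cell receptor, at 4.26 and 4.63, and Alas2, the first enzyme of haem synthesis in erythroid cells, at 7.24 and 7.54. The spleen control arrays had 4.85 and 4.80 for Cd79a and 7.51 and 7.24 for Alas2. So on 5 arrays the markers of the label's own tissue stood low and those of another tissue high. Alb was also at 6.95 and 6.91 on the lung late arrays and Amy2a5 between 5.91 and 7.24 on the infected spleens, beside high levels of these tissues' own markers. Replicates correlated across genes at 0.989, 0.992 and 0.99 in the 3 spleen groups, at 0.994 and 0.993 in lung onset and late, and at 0.982 in liver late, but at 0.73 in lung control, 0.743 in liver control and 0.767 in liver onset. No array was relabelled. The 6 spleen arrays all carried spleen markers, with Cd79a between 3.57 and 4.85, so the spleen comparisons rest on arrays that match their labels. Lung late against onset does too. Every comparison of lung or liver with control rests on arrays at odds with their labels, and no direction of infection is drawn from them.

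**Figure D1:**
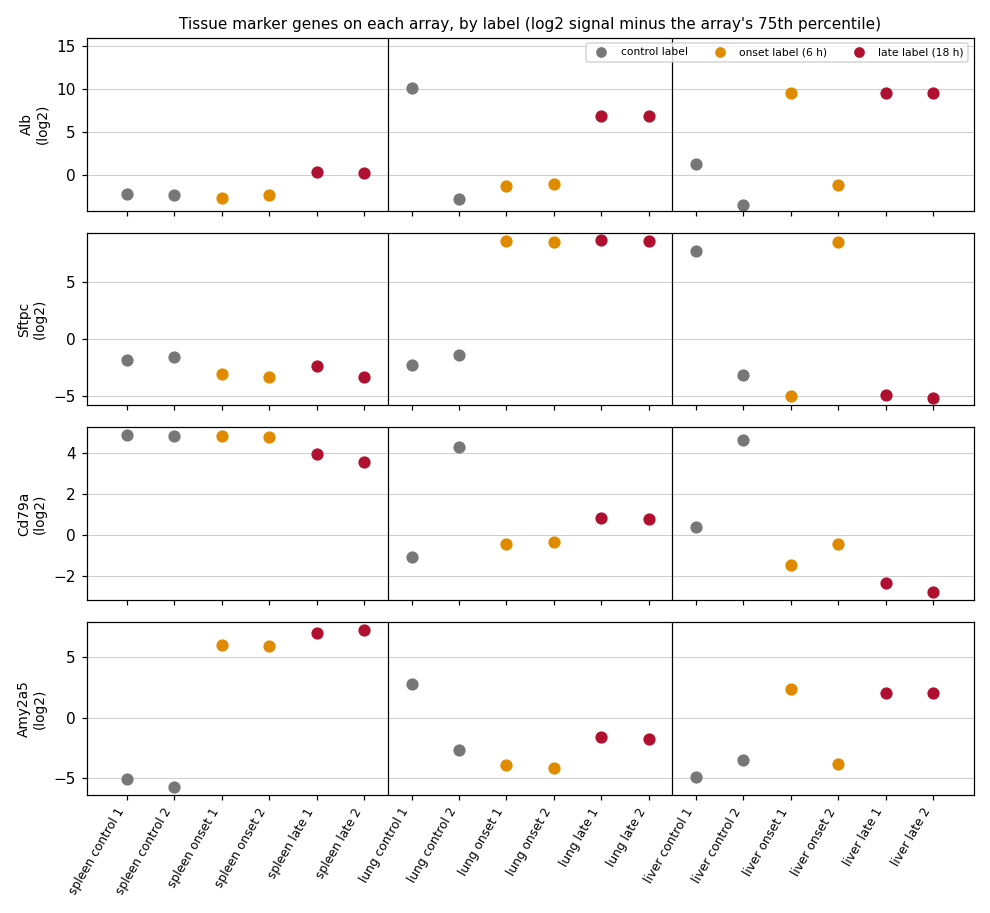
Levels of 4 marker genes (Alb of hepatocytes, Sftpc of lung epithelium, Cd79a of B cells, Amy2a5 of exocrine pancreas) on each of the 18 arrays, 1 point per array, in log2 relative to the array's 75th percentile and ordered by label. The array labelled lung control 1 has Alb at 10.11, the arrays labelled liver control 1 and liver onset 2 have Sftpc at 7.65 and 8.51, and Amy2a5 lies between 5.91 and 7.24 on the infected spleens against -5.04 and -5.74 on the spleen controls.

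Genes of inflammatory mediators were raised in the spleen at 6 h. Il6, the cytokine that drives the acute phase response, rose by 7.82 log2 (SE 0.67, adjusted p = 5.4e-05, n = 2 against 2) and was above background on only 1 of the 2 control arrays. Cxcl1, which attracts neutrophils, rose by 7.37 (SE 0.76, adjusted p = 0.00045), Tnf by 4.21 (SE 0.50, adjusted p = 0.00088) and Il1b by 3.64 (SE 0.23, adjusted p = 6.9e-06). Genes of pancreatic digestive enzymes rose even further, with the trypsinogen Try5 higher by 10.28 (SE 0.80, adjusted p = 4.7e-05). Ptgds, a prostaglandin D synthase, fell by 4.57 (SE 0.60, adjusted p = 0.0019), and Ccr3, the eotaxin receptor of eosinophils, fell by 3.72 (SE 0.42, adjusted p = 0.00087). Unless another fit is named, rose and fell here and in what follows refer to limma's fit over all 18 arrays.

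In that fit 164 genes rose and 22 fell of 17147 tested in spleen onset, which lies with its controls on 1 slide. Fitted on the 6 spleen arrays alone, 2323 rose and 4750 fell, and without the 5 arrays at odds with their labels, 2619 rose and 5153 fell. All 186 calls of the 18-array fit were also made in both of these fits. The spleen folds are the same in each fit, so the signs could not differ. The median residual SD was 0.61 log2 in the 18-array fit, 0.159 in the spleen fit and 0.154 without the 5 arrays. The spread of the 18-array fit takes in lung control, liver control and liver onset, whose arrays carry markers of different tissues. Its SEs and adjusted p-values for spleen therefore do not measure the spread between spleen pools alone. The total of 186 became 69 without spleen control 1, 71 without spleen control 2, and 65 without either onset array. It was 628 on the arrays of slide 1 alone, 701 with the slide as a fixed term and 357 with the scan session as a random block.

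The list of exocrine pancreas markers moved most in size. All 19 measured members rose, with a median of 9.36 log2 (camera adjusted p = 8.8e-82, and adjusted p = 0.00016 with an estimated correlation), and the median was again 9.36 with the 6 members below background in the controls set at their bounds. Amylase Amy2a5 rose by 11.33, the trypsinogens Try4 by 10.50 and Prss2 by 9.70, elastase Cela3b by 9.36 and carboxypeptidase Cpa1 by 9.89, while carboxypeptidase Cpb1 was at least 1890-fold higher, the lipase-related Pnliprp1 at least 1230-fold and pancreatic lipase Pnlip at least 709-fold. Exocrine genes outside the list rose with it, elastase Cela3a by 10.04, the zymogen granule protein Sycn by 9.27 and amylase Amy1 by 9.14, and the lithostathine genes Reg1 and Reg2 were at least 2650-fold and 1880-fold higher. Both onset pools shared the rise, since the list's median differed by -0.03 between them.

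Cytokine genes rose in 9 of 22 measured members (16 adjusted over the list alone), with a median of 2.38, or 2.07 with genes at their bounds (camera adjusted p = 8.2e-30, 0.00088 with an estimated correlation). Csf3, the granulocyte growth factor, was at least 35.9-fold higher. Chemokine genes rose in 7 of 24 members and fell in 1, Ccl6, a chemokine of myeloid cells, by 2.74 (14 and 3 adjusted over the list alone; median 2.91, 2.73 with bounds; camera adjusted p = 4.2e-21, 8.8e-05 with an estimated correlation). Ccl3 rose by 6.15 and the monocyte attractant Ccl2 by 5.81, and the neutrophil attractant Cxcl2 was at least 31.7-fold higher. Cxcl10, an interferon-induced T cell attractant, rose by 3.81.

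Type I interferon response genes rose in 10 of 30 members (23 adjusted over the list alone), median 1.51 (1.44 with bounds; camera adjusted p = 1.2e-33, 0.011 with an estimated correlation), among them the antiviral Ifit1 (3.14), Mx2 (2.72) and Ifi44 (2.06) and the feedback protease Usp18 (2.68). Interferon-gamma response genes rose in 3 of 21 (7 over the list alone), median 1.1 (camera adjusted p = 1.1e-15, 0.024 with an estimated correlation). These were Acod1, which makes itaconate (3.98), the guanylate-binding protein Gbp5 (2.93) and the checkpoint ligand Cd274 (2.09). NF-kB and Toll-like receptor genes rose in 8 of 29 (16 over the list alone), median 1.15 (camera adjusted p = 2.5e-22, 0.021 with an estimated correlation), including the inhibitors Tnip3 (3.83) and Tnfaip3 (3.36), the lipopolysaccharide co-receptor Cd14 (3.70) and Nfkbiz (2.53). STAT3 and SOCS feedback genes rose in 3 of 18 (6 over the list alone), median 0.87 (camera adjusted p = 3.6e-12, 0.0004 with an estimated correlation), namely the decoy receptor Il1r2 (3.79), Socs3 (3.12) and Cebpd (1.99). Endothelial activation and coagulation genes rose in 7 of 21 (9 over the list alone), median 1.54 (camera adjusted p = 1e-14, 0.024 with an estimated correlation). Among them were the aggrecanase Adamts4 (6.07), cyclooxygenase Ptgs2 (4.67) and the metalloproteinase inhibitor Timp1 (2.72).

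Adipocyte markers fell in 2 of 15 members (3 over the list alone), the lipid droplet gene Cidec by 4.07 and the nuclear receptor Pparg by 1.55, with a list median of -1.55, or -1.33 with bounds (camera adjusted p = 4.4e-06, 0.025 with an estimated correlation). Other falls were those of the pattern-recognition protein Spon2 by 3.61, the mannose receptor Mrc1 of macrophages by 2.53, the ferrireductase Steap3 by 2.16 and the nuclear lamin Lmna by 1.95. Dct, an enzyme of melanin synthesis, was at least 361-fold lower, Trmt9b at least 5.93-fold, Hebp2 at least 3.60-fold and the ARF-like GTPase gene Arl11 at least 2.93-fold. These groups moved in the same spleens in which the pancreas list stood 9.36 higher.

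Over 18 arrays a further 14 lists passed camera at the preset correlation and not with an estimated one. Of these, acute phase and cell cycle lists did pass with an estimated correlation without the 5 arrays, as given below. Acute phase proteins had 1 riser of 27 in the 18-array fit and 19 in the spleen fit (median 1.48, adjusted p = 8.4e-06, 0.69 with an estimated correlation). That riser was Saa3, a serum amyloid made outside the liver too, by 4.15 (SE 0.60, adjusted p = 0.0041). Glucocorticoid response genes had 0 calls in limma's 18-array fit (8 at an unadjusted p under 0.05; 2 adjusted over the list alone) and 13 risers and 1 faller of 17 in the spleen fit (median 1.1, adjusted p = 4.1e-08, 0.13 with an estimated correlation). Cell cycle genes had 0 calls of 29 (0 at an unadjusted p under 0.05) and 27 fallers in the spleen fit (median -1.12, adjusted p = 0.0025, 0.94 with an estimated correlation). Inflammasome genes had 2 risers of 14, Mefv (2.32) and the lipopolysaccharide-sensing caspase Casp4 (1.90), with 3 over the list alone (adjusted p = 0.00018, 0.28 with an estimated correlation). Neutrophil markers had 3 risers of 26 (5 over the list alone), the pattern receptor Clec4e (3.41) and the formyl peptide receptors Fpr1 (2.28) and Fpr2 (2.18), all of which macrophages also use, while the neutrophil granule gene S100a8 stood at 0.38 (SE 1.23, adjusted p = 1), and the list's median was 0.18 (adjusted p = 5.8e-05, 0.69 with an estimated correlation). Macrophage markers had 1 faller of 20, Mrc1, and 3 over the list alone (median -0.73, adjusted p = 0.014, 0.69 with an estimated correlation). T and NK cell markers had 1 riser of 25, the cytotoxic protease Gzmb (1.82), and 2 over the list alone (adjusted p = 0.0097, 0.94 with an estimated correlation). The p53 list had 1 riser of 24, the stress gene Gadd45b (2.36), and 3 over the list alone (adjusted p = 0.0042, 0.095 with an estimated correlation). The hypoxia and glycolysis list had 1 of 22, the glycolytic regulator Pfkfb3 (1.94), and 3 over the list alone (adjusted p = 0.0021, 0.31 with an estimated correlation).

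Each of the remaining 5 such lists had 0 members called by limma over 18 arrays. Unfolded protein response genes had a median of 0.30 (1 at an unadjusted p under 0.05 and 1 over the list alone; adjusted p = 0.014, 0.94 with an estimated correlation), heat shock proteins 0.46 (1 and 1; adjusted p = 0.022, 0.31 with an estimated correlation), endothelial markers -0.78 (3 unadjusted; adjusted p = 0.037, 0.94 with an estimated correlation), fibroblast and matrix genes -1.05 (2 unadjusted; adjusted p = 0.0072, 0.69 with an estimated correlation) and mesothelial markers -1.28, or -0.97 with bounds (0 unadjusted; adjusted p = 0.017, 0.69 with an estimated correlation). In the spleen fit 12 of 19 endothelial, 16 of 20 fibroblast and 9 of 13 mesothelial genes fell, and 9 of 23 unfolded protein genes and 7 of 13 heat shock genes rose. Erythroid markers did not pass (median -1.25, adjusted p = 0.086), although 20 of 22 fell in the spleen fit. The other 20 lists did not pass either. They were megakaryocyte and platelet markers, MHC class I and the mitochondrial respiratory chain (adjusted p = 0.14 each), B cells (0.23), cholesterol synthesis and muscle markers (0.45 each), iron handling (0.72), NRF2 genes (0.73), lipogenesis (0.85), ribosomal proteins, hepatocyte secreted proteins and cytochrome P450 genes (0.89 each), the circadian clock (0.92), and fatty acid oxidation, bile acid genes, gluconeogenesis, lung epithelium, dendritic cells, MHC class II and complement (0.97 each). For the clock, ribosomal, P450 and MHC class II lists the medians (-0.17, -0.08, -0.05 and -0.11) and means were negative while camera's direction was up. The hepatocyte and dendritic lists had means of -0.06 and -0.16 against a direction of up.

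With an estimated correlation, these list calls depend on which arrays enter. In the spleen fit 0 of 44 lists passed camera in that form at onset (lowest adjusted p = 0.062, for pancreas, type I interferon, acute phase, cell cycle and erythroid lists), with cytokines and interferon-gamma genes at 0.069, NF-kB genes at 0.083, adipocyte markers at 0.15, chemokines and endothelial activation at 0.19 and STAT3 genes at 0.20. Without the 5 arrays pancreas markers (0.0011), cytokines, type I interferon genes and acute phase proteins (0.0076 each), interferon-gamma genes, NF-kB genes and adipocyte markers (0.031 each), erythroid markers (0.033), cell cycle genes (0.042) and B cell markers (0.049) passed, and chemokines, STAT3 genes and endothelial activation (0.067 each) did not.

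At 18 h the infected spleen carried the same kinds of raised genes at other sizes. Il6 rose by 8.37 log2 (SE 0.67, adjusted p = 2.1e-05, n = 2 against 2), Cxcl1 by 7.32 (SE 0.76, adjusted p = 0.00033), Saa3 by 5.43 (SE 0.60, adjusted p = 0.00032) and the anti-inflammatory cytokine Il10, above background on 1 of the 2 control arrays, by 4.91 (SE 0.44, adjusted p = 5e-05). Pancreatic enzymes rose further, with trypsinogen Prss2 up by 11.29 (SE 0.94, adjusted p = 2.3e-05). Mgst3, a microsomal glutathione transferase, fell by 4.58 (SE 0.80, adjusted p = 0.011), and Smim1, which carries the Vel blood group antigen of red cells, fell by 4.47 (SE 0.64, adjusted p = 0.0025).

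In spleen late 259 genes rose and 56 fell of 17153 tested. The spleen arrays alone gave 3492 and 4410, and the fit without the 5 arrays 3884 and 4637, and both made all 315 calls from the same folds. The total became 121 without spleen control 1, 125 without spleen control 2, 121 without late 1 and 114 without late 2. The late arrays lie on another slide than their controls, and the total was 3021 with the slide as a fixed term and 100 with the scan session as a random block. With normexp 273 rose and 130 fell.

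All 19 pancreas markers rose again, with a median of 10.36 log2, also with 6 members at their bounds (camera adjusted p = 3.3e-68, 0.00034 with an estimated correlation), and the medians of the pools differed by 0.09. Amy2a5 rose by 12.51, Cela3b by 11, Try5 by 10.82, Try4 by 10.76, Cpa1 by 10.36 and chymotrypsinogen Ctrb1 by 10.12, and trypsinogen Prss1 was at least 3340-fold higher, Cpb1 at least 3170-fold and Pnlip at least 1560-fold. Outside the list Cela3a rose by 11.21 and Sycn by 11.07, and Reg2 was at least 6890-fold higher, Reg1 at least 5800-fold, the mucosal scavenger receptor Dmbt1 at least 5070-fold and the antimicrobial lectin Reg3b at least 4600-fold.

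Cytokine genes rose in 10 of 22 (15 adjusted over the list alone; median 2.49; camera adjusted p = 1.4e-24, 0.0018 with an estimated correlation). Csf3 was at least 98.6-fold higher and Il17a, a cytokine of T helper 17 cells, at least 7.67-fold. Il1b rose by 2.77 (SE 0.23, adjusted p = 2.3e-05) and Tnf by 2.22 (SE 0.50, adjusted p = 0.048). Chemokine genes rose in 12 of 24 (16 and 1 faller over the list alone; median 3.39, 3.25 with bounds; camera adjusted p = 4.3e-22, 6.9e-05 with an estimated correlation). Cxcl2 was at least 83.1-fold higher and Cxcl3 at least 27.4-fold, while Ccl2 rose by 5.34 and Cxcl10 by 3.02. Endothelial activation genes rose in 8 of 21 (11 over the list alone; median 2.17, 2.02 with bounds; camera adjusted p = 1.3e-16, 0.025 with an estimated correlation), with Adamts4 at 6.10, Ptgs2 at 5.11 and the vasoconstrictor Edn1 at 4.55.

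**Figure D2:**
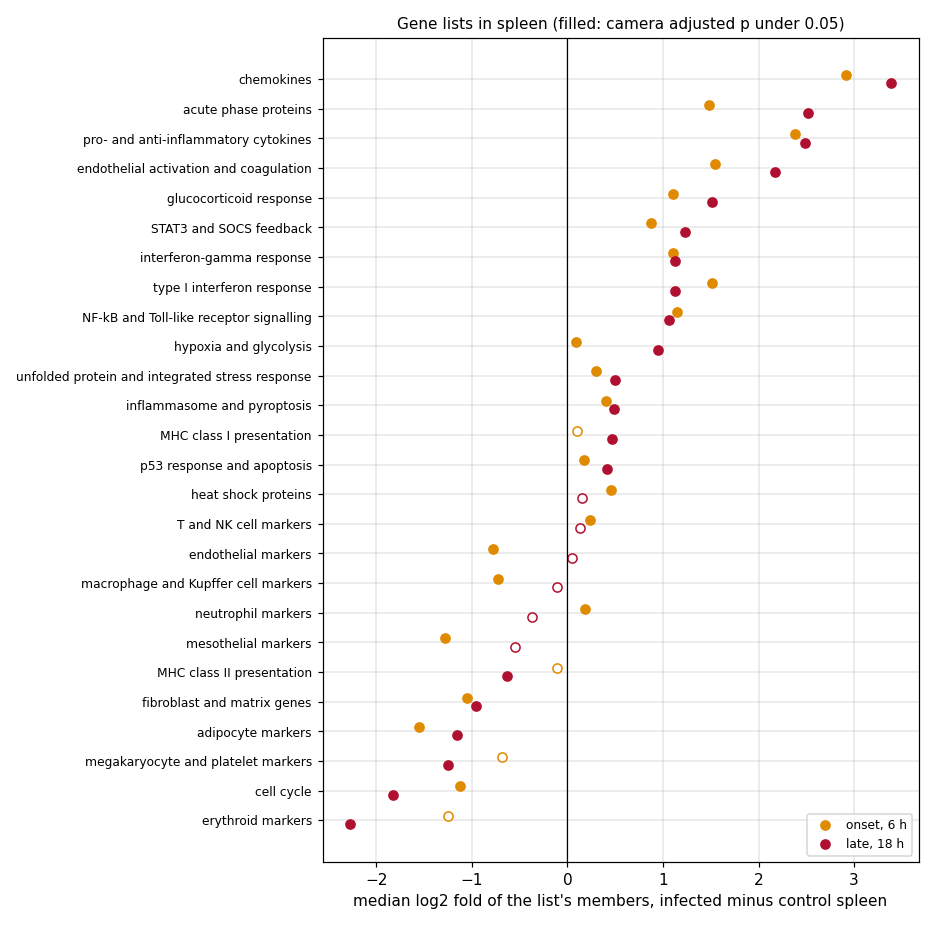
Median log2 fold change of each gene list in the infected spleen against control, at onset and at the late stage, with filled points where camera's adjusted p was under 0.05 at the preset correlation. The exocrine pancreas list (medians 9.36 and 10.36) is left out so that the other lists can be read. Chemokines reach 2.91 and 3.39, and erythroid markers -1.25 and -2.28.

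Hypoxia and glycolysis genes rose in 6 of 22 (9 over the list alone, 18 in the spleen fit; median 0.95; camera adjusted p = 2.4e-11, 0.033 with an estimated correlation). Adrenomedullin Adm stood at 4.06, Pfkfb3 at 2.97, Hif1a at 2.26 and the glucose transporter Slc2a1 at 2.01. STAT3 feedback genes rose in 3 of 18 (9 over the list alone; median 1.23; camera adjusted p = 8.7e-11, 0.00069 with an estimated correlation), Il1r2 by 4.21, Socs3 by 3.66 and the oncostatin M receptor Osmr by 1.94. Interferon-gamma genes rose in 7 of 21 (9 over the list alone; median 1.13; camera adjusted p = 2.4e-13, 0.042 with an estimated correlation), among them Acod1 (4.62), Cd274 (3.36), Gbp5 (3.10) and nitric oxide synthase Nos2 (2.99). NF-kB genes rose in 10 of 29 (17 over the list alone; median 1.06; camera adjusted p = 2.6e-16, 0.042 with an estimated correlation), with Tnip3 at 4.36, Cd14 at 4.0, Tnfaip3 at 3.49 and the inhibitory kinase Irak3 at 2.64. Type I interferon genes rose in 6 of 30 (21 over the list alone; median 1.13; camera adjusted p = 1.3e-16), among them the nucleic acid sensor Zbp1 (2.20), Mx2 (2.04), Ifit1 (2.02) and Ifit2 (1.28), and this call was lost at adjusted p = 0.052 with an estimated correlation.

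Over 18 arrays some lists passed camera only at the preset correlation. Among these, the erythroid, cell cycle, acute phase and platelet lists passed with an estimated correlation in other fits, as given below. Of 22 erythroid markers 0 were called by limma over 18 arrays (3 at an unadjusted p under 0.05) and 21 fell in the spleen fit. Their median was -2.28 (camera adjusted p = 0.00029, 0.80 with an estimated correlation). The erythroid enzyme gene Alas2, for one, stood at 6.44 and 6.22 on the late arrays. Of 29 cell cycle genes 0 were called (3 unadjusted) and all 29 fell in the spleen fit (median -1.83, adjusted p = 3.5e-07, 0.76 with an estimated correlation). Acute phase proteins had 1 riser of 27, Saa3, and 23 in the spleen fit (median 2.52, 2.04 with bounds; adjusted p = 1.8e-08, 0.64 with an estimated correlation). Glucocorticoid response genes rose in 3 of 17 (10 over the list alone; median 1.51; adjusted p = 1.6e-10, 0.071 with an estimated correlation), namely the phosphatase Dusp1 (2.94), Pdk4 (2.90), which spares glucose, and transglutaminase Tgm2 (2.15). Platelet markers had 0 of 16 called (1 unadjusted) and 13 fallers in the spleen fit (median -1.25, adjusted p = 0.017, 0.82 with an estimated correlation). MHC class II genes had 0 of 12 called (3 unadjusted) and 9 fallers in the spleen fit (median -0.63, adjusted p = 0.019, 0.62 with an estimated correlation). MHC class I genes had 0 of 16 called (2 unadjusted) and 10 risers in the spleen fit (median 0.47, adjusted p = 0.01, 0.82 with an estimated correlation). Fibroblast genes had 0 of 20 called (3 unadjusted; median -0.96, adjusted p = 0.029, 0.82 with an estimated correlation).

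Pparg fell by 1.57 as 1 of 15 adipocyte markers (2 over the list alone; median -1.16, adjusted p = 0.019, 0.28 with an estimated correlation). Gadd45b rose by 2.34 as 1 of 24 p53 genes (2 over the list alone; adjusted p = 0.001, 0.052 with an estimated correlation), and the stress factor Atf3 rose by 2.76 as 1 of 23 unfolded protein response genes (2 over the list alone; adjusted p = 0.0011, 0.80 with an estimated correlation). Mefv (2.05) and Casp4 (1.59) rose as 2 of 14 inflammasome genes (adjusted p = 0.019, 0.66 with an estimated correlation). The other 23 lists did not pass: the circadian clock (adjusted p = 0.09), muscle (0.13), complement (0.23), neutrophils and iron handling (0.25 each), dendritic cells (0.28), cholesterol synthesis and hepatocyte proteins (0.30 each), mesothelium (0.32), T and NK cells (0.36), heat shock proteins (0.43), gluconeogenesis and B cells (0.56 each), the respiratory chain (0.61), fatty acid oxidation, lipogenesis, bile acid genes, NRF2 genes, ribosomal proteins and endothelium (0.66 each), P450 genes and macrophages (0.71 each) and lung epithelium (0.87). Among them the neutrophil list had a median of -0.37 and a mean of -0.19 against a direction of up, and bile acid genes and lipogenesis had medians of 0.03 and 0.16 against a direction of down. S100a8 stood at -0.44 (adjusted p = 0.98) and the haem-degrading enzyme gene Hmox1 at 2.39 (SE 1.38, adjusted p = 0.61), after 2.52 at onset (adjusted p = 0.77). Further falls were those of Ppfia4 (-3.89), fructosamine kinase Fn3k (-3.82), Svip (-3.55), Ccr3 (-3.49), Ccdc80 (-3.40) and Ptgds (-3.14). Bounds were at least 9.34-fold lower for the macrophage chitinase Chit1, 8.67-fold for Abca9, 4.23-fold for Ccn5 and 3.44-fold for the scavenging chemokine receptor Ackr4.

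In the spleen fit with an estimated correlation, 4 lists passed camera late, pancreas, acute phase, erythroid and cell cycle (adjusted p = 0.048 each). Hypoxia genes (0.081), type I interferon genes (0.085), cytokines, interferon-gamma genes and platelet markers (0.088 each), NF-kB genes (0.11), chemokines and endothelial activation (0.19 each) and STAT3 genes (0.25) did not. Without the 5 arrays pancreas (0.0023), acute phase (0.0063), cytokines and erythroid markers (0.016 each), type I interferon and cell cycle genes (0.025 each), hypoxia (0.026), interferon-gamma genes and platelet markers (0.043 each) passed, and NF-kB genes (0.051), chemokines and endothelial activation (0.064 each) and STAT3 genes (0.10) did not.

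Onset and late calls in the spleen shared 139 of 164 and 259 raised genes and 12 of 22 and 56 lowered genes. Independent lists of these sizes would share 2.48 and 0.0718, and unchanged groups simulated against the same 2 controls shared 0 in each direction. With no gene changed, the simulation makes almost no calls, so its 0 was set in advance. It cannot tell how much the shared controls add. The pancreas markers, which all rose at both stages, are among the shared raised genes. In the spleen fit 1616 raised and 3074 lowered genes were shared (473 and 1220 for independent lists), and 273 were called with opposite signs. The fold changes correlated at 0.791 across genes, which are not independent replicates (0.5 simulated), with a covariance of 0.888 (0.371 simulated with the 18-array spread and 0.0434 with the spleen spread). The 2 controls cannot be split, so part of any excess may come from sharing them.

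Between 6 h and 18 h the 18-array fit called few genes in the spleen. The kallikrein genes Klk1b24, Klk1b5 and Klk1b3 encode serine proteases of glandular tissue. Klk1b24 rose by 2.74 log2 (SE 0.41, adjusted p = 0.046, n = 2 against 2), Klk1b5 by 2.45 (SE 0.37, adjusted p = 0.047) and Klk1b3 by 2.26 (SE 0.31, adjusted p = 0.045), and Fcgr4, an activating receptor for immunoglobulin G, rose by 2.13 (SE 0.25, adjusted p = 0.024). Rfesd fell by 3.39 (SE 0.38, adjusted p = 0.023) and Pip5kl1 by 3.07 (SE 0.34, adjusted p = 0.023). In all 6 genes rose and 4 fell, all also called, from the same folds, in the spleen fit, where 3382 rose and 2133 fell. Without any 1 of the 4 arrays 0 genes passed (309 to 385 at an unadjusted p under 0.05 in limma), and the stages lie on different slides. In the spleen fit, Tnf fell by 1.99 (adjusted p = 3.9e-05), Il1b fell by 0.87 (0.0011), Cxcl10 fell by 0.79 (0.012) and S100a8 fell by 0.81 (0.013), while Saa3 rose by 1.28 (0.00035) and Il6 by 0.55 (0.0092), and Cxcl1 stood at -0.05 (0.80) and Hmox1 at -0.13 (0.91). That fit raised 17 of 22 hypoxia genes, 14 of 19 endothelial markers, 19 of 27 acute phase proteins and 13 of 27 complement genes, beside 17 of 19 pancreas markers (median 0.98). Liver genes rose too. The spleen fit raised 9 of 21 hepatocyte secreted proteins (median 1.12, 0.73 with bounds) and lowered 2. Of 21 gluconeogenesis and amino acid genes it raised 10 and lowered 2 (median 0.84). Alb stood at -2.63 and -2.33 on the spleen onset arrays and at 0.43 and 0.25 on the late arrays. The same fit lowered 21 of 29 cell cycle genes, 19 of 22 erythroid markers, 14 of 18 B cell markers, 15 of 26 neutrophil markers, 16 of 30 type I interferon genes and 8 of 12 MHC class II genes.

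In the lung, the genes with the largest rises from onset to late included Lor, Tnnc2, Acta1 and Serpinb3c. Lor, the loricrin of cornified epithelium, rose by 7.44 log2 (SE 0.40, adjusted p = 3e-05, n = 2 against 2), fast skeletal troponin Tnnc2 by 7.34 (SE 0.91, adjusted p = 0.0037), skeletal actin Acta1 by 7.18 (SE 0.54, adjusted p = 0.00032) and the serpin Serpinb3c by 6.99 (SE 0.75, adjusted p = 0.0014). The list of cardiac and skeletal muscle markers had medians of 0.27 and 0.31 on the lung onset arrays and 3.1 and 3.05 on the late arrays. Whether these transcripts came from lung cells or from other tissue in the samples was not tested. The T and NK cell chemokine Xcl1 fell by 2.49 (SE 0.46, adjusted p = 0.042). In all 68 genes rose and 2 fell. Left out in turn, onset 1, onset 2, late 1 and late 2 brought the total of 70 to 19, 14, 12 and 14. The lung arrays alone, whose controls are at odds with their labels, gave 0 calls (1156 at an unadjusted p under 0.05 in limma). The fit without the 5 arrays, which has the same folds, raised 2880 genes and lowered 3061, including all 70.

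In that last fit hepatocyte transcripts were higher in the late lung. Alb stood at 6.95 and 6.91 on the late arrays and at -1.25 and -1.01 on the onset arrays, and the apolipoprotein Apoa1 at 2.82 and 2.86 against -5.86 and -6.62. Hepatocyte secreted proteins rose in 20 of 21 members (median 6.94), gluconeogenesis and amino acid genes in 20 of 21 (3.79, 3.57 with bounds), cytochrome P450 genes in 15 of 20 (3.36, 3.09 with bounds), acute phase proteins in 24 of 27 (2.42), complement genes in 19 of 27 and muscle markers in 11 of 21 (1.68, with 4 also called over 18 arrays). Beside these shifts, 15 of 21 endothelial activation genes (3 over 18 arrays), 12 of 22 hypoxia genes, 14 of 24 chemokines and 11 of 22 cytokines (2 over 18 arrays) rose, and 7 chemokines and 6 cytokines fell. Il6 rose by 2.51 (adjusted p = 2.9e-08, and 0.28 over 18 arrays), Cxcl1 by 1.24 (4.6e-06), Saa3 by 0.62 (0.0042) and Hmox1 by 2.53 (0.0089), while Il1b fell by 0.74 (0.00012), Cxcl10 fell by 0.77 (0.0022), S100a8 fell by 0.49 (0.029) and Tnf fell by 0.37 (0.0095). T and NK cell markers fell in 18 of 25, neutrophil markers in 15 of 26, fibroblast genes in 13 of 20, platelet markers in 11 of 16 and heat shock genes in 8 of 13. These lists were counted by member and not tested as sets, and the stages lie on different slides.

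In the liver, Il1b, Ccnd1, Gpr84, Sirpb1a and Clec7a were lower at 18 h than at 6 h. Over 18 arrays Il1b fell by 2.11 log2 (SE 0.23, adjusted p = 0.0081, n = 2 against 2), cyclin Ccnd1 fell by 3.36 (SE 0.45, adjusted p = 0.014), Gpr84, a fatty acid receptor of activated macrophages, fell by 2.90 (SE 0.26, adjusted p = 0.0025), Sirpb1a fell by 2.85 (SE 0.42, adjusted p = 0.021) and the fungal sugar receptor Clec7a fell by 2.69 (SE 0.34, adjusted p = 0.01). Igdcc4 rose by 4.97 (SE 0.70, adjusted p = 0.018), the adrenergic receptor Adra2a by 3.73 (SE 0.45, adjusted p = 0.0088), Igsf23 by 3.10 (SE 0.46, adjusted p = 0.022) and the hypoxia-induced lipid droplet gene Hilpda by 2.89 (SE 0.44, adjusted p = 0.025). The onset mean includes the array labelled liver onset 2, which carries lung markers. Without it, with n = 1 at onset and the spread of the other groups assumed for it, the differences were -2.22 for Il1b (adjusted p = 3.2e-07), -2.92 for Ccnd1, -2.88 for Gpr84, -2.37 for Sirpb1a, -2.29 for Clec7a, 4.02 for Igdcc4, 3.66 for Adra2a, 3.52 for Igsf23 and 2.90 for Hilpda.

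In total 15 genes rose and 14 fell over 18 arrays. The total of 29 became 2723 without liver onset 1 (885 rose, 1838 fell), 35 without liver onset 2 (27 rose, 8 fell), 6 without late 1 and 0 without late 2 (835 at an unadjusted p under 0.05 in limma), and the fit of the 6 liver arrays gave 0 calls (511 unadjusted). Without the 5 arrays 2839 rose and 3055 fell, including all 29. In that fit, with liver onset 1 as the only onset array, 16 of 20 cytochrome P450 genes fell (median -1.94), as did 18 of 25 cholesterol synthesis genes (-0.81), 11 of 16 lipogenesis genes (-1.26), 15 of 20 NRF2 antioxidant genes (-0.88), 21 of 26 neutrophil markers (-1.25), 17 of 29 NF-kB genes (-0.53) and 8 of 12 MHC class II genes (-1.47). Cell cycle genes fell in 6 of 29 and rose in 3 (-0.12), cytokines fell in 7 of 22 and rose in 8 (0.42), and chemokines fell in 10 of 24 and rose in 8 (-0.21). Rises were counted in 12 of 20 circadian clock genes (1.09), 11 of 22 hypoxia genes (0.38) and 9 of 19 endothelial markers (0.59). Tnf fell by 2.12 (adjusted p = 4e-07), S100a8 fell by 1.27 (0.00042) and Il6 fell by 1.09 (8.1e-05), Cxcl10 rose by 0.55 (0.037), and Cxcl1 (-0.33, 0.051), Saa3 (0.23, 0.31) and Hmox1 (-0.30, 0.79) did not pass. A single onset pool and a different slide limit these values. The hour of collection differs between the stages too and was not separated from them.

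Lung against the arrays labelled lung control, 1 with liver markers and 1 with spleen markers, gave differences that mix tissue and infection. At onset Il1b was 4.56 log2 higher (SE 0.23, adjusted p = 1.6e-06, n = 2 against 2), Clec4e 4.90 higher and Ccl2 4.88 higher. The neutrophil collagenase Mmp8 (5.14), the small heat shock protein Hspb1 (5.04) and the scaffold gene Akap12 (4.99) were also higher, while the liver iron sensor Tfr2 (-9.0), the erythroid factor Klf1 (-7.39) and the macrophage gene Cd5l (-7.39) were lower. At the late stage Timp1 (5.56), Akap12 (5.38) and Ccl2 (5.32) were higher, and Il6 was at least 149-fold higher. The calls were 741 higher and 493 lower at onset and 687 and 452 late, and 592 of 1234 and 539 of 1139 were also made by the lung arrays alone. Of 44 lists 32 passed camera at onset and 27 late, and 2 and 3 with an estimated correlation. Chemokine genes were higher in 14 of 24 at onset and 16 of 24 late (estimated-correlation camera adjusted p = 0.00031 and 0.00019), and STAT3 feedback genes in 12 and 10 of 18 (0.00031 and 0.00023). Endothelial activation genes were higher in 13 and 14 of 21 (0.054 and 0.018). The fit of the 6 lung arrays lost these calls in the same form, with chemokines at adjusted p = 0.14 and 0.13, STAT3 genes at 0.14 and 0.13 and endothelial activation at 0.37 and 0.24. Lung epithelial markers differed by a median of 5.65 and 4.81, or 4.79 and 3.78 with the 9 members at a bound set there, in 3 of 23 genes each (adjusted p = 8.4e-10 and 2.2e-09, 0.45 and 0.46 with an estimated correlation).

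Without lung control 1 the onset total of 1234 became 2844, without lung control 2 4545, without onset 1 163 and without onset 2 142. The late total of 1139 became 3116, 3722, 174 and 200 without lung control 1, lung control 2, late 1 and late 2. With 1 lung control left out most calls were lower: 1452 of the 2844 and 2724 of the 4545 at onset, and 1726 of the 3116 and 2157 of the 3722 late. Against the single lung control array on the same slide (n = 2 against 1), the onset total was 4055 on slide 1 (1448 higher, 2607 lower) and the late total 11351 on slide 2 (4990 higher, 6361 lower). With the slide as a fixed term they were 5365 (1822 higher, 3543 lower) and 2650, and with the session as a random block 118 and 1809. Quantile normalisation moved the median gene from -0.234 to 0.205 at onset and from -0.281 to 0.147 late, with 1585 higher and 385 lower calls and 1397 and 360. Normexp gave 1785 higher and 2882 lower at onset and 1396 and 2060 late.

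Liver against the arrays labelled liver control, 1 with lung markers and 1 with spleen markers, mixes tissue and infection likewise, and 1 of the liver onset arrays carries lung markers. At onset Saa3 was 6.33 log2 higher (SE 0.60, adjusted p = 0.00019, n = 2 against 2), the acute phase serpin Serpina3n 6.77, Ccl2 6.15, Cd14 6.10 and Gpr84 5.41. At the late stage the inhibitor chain gene Itih3 was 10.02 higher, Serpina3n 9.11 and Cd14 7.30, and the B cell gene Cd79b was lower (-5.21). The calls were 533 higher and 360 lower at onset and 2003 and 1431 late, and the 6 liver arrays alone gave 0 for both (1907 and 3375 at an unadjusted p under 0.05 in limma). Of 44 lists 33 passed camera at onset and 36 late, and 2 each with an estimated correlation. Chemokine genes were higher in 10 and 12 of 24 (estimated-correlation camera adjusted p = 0.00075 and 0.0076) and STAT3 feedback genes in 13 and 11 of 18 (0.00054 and 0.0076). The fit of the 6 liver arrays lost both, at adjusted p = 0.096 each at onset and 0.17 each late. Acute phase proteins were higher in 7 and 22 of 27 (adjusted p = 3.4e-10 and 1e-11, 0.47 and 0.38 with an estimated correlation), beside hepatocyte secreted proteins whose median was 4.28 and 9.16 higher.

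Without liver control 1 the onset total of 893 became 2160, without liver control 2 4118, without onset 1 551 and without onset 2 4302. The late total of 3434 became 3330, 6003, 259 and 241 without liver control 1, liver control 2, late 1 and late 2. The balance turned without liver control 1, to 705 higher and 1455 lower at onset and 1242 and 2088 late, with a median gene of -0.218 and -0.268, and without onset 2, to 2004 and 2298. Against the single liver control array on the same slide (n = 2 against 1), the onset total was 3683 on slide 1 (1278 higher, 2405 lower) and the late total 11940 on slide 2. With the slide as a fixed term the onset total was 5056 (2107 higher, 2949 lower), and with the session as a random block it was 79. Quantile normalisation moved the median gene from 0.156 to 0.418 at onset and from 0.121 to 0.305 late, with 804 higher and 126 lower calls and 2080 and 868. Normexp moved the onset median to 0.051 and gave 1765 higher and 529 lower late, and the authors' values gave 638 higher and 820 lower at onset.

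Whether the response differed between tissues was tested as labelled. The F test called 55 of 17142 genes at onset and 131 of 17148 late, and 21 and 54 genes were called with opposite signs in 2 tissues. Of the latter, Reg2, not well above background in spleen controls, was at least 1880-fold higher in spleen at onset (adjusted p = 3.8e-05) and at least 6890-fold late (adjusted p = 1.4e-05), and was not well above background in infected lung or liver. In the panel, Il1b late was 2.77 higher in spleen, 3.81 in lung and 2.30 in liver, with lung above liver by 1.51 (SE 0.32, adjusted p = 0.012), and Cxcl10 late was 3.02, 2.89 and 4.94, with liver above spleen (-1.92, SE 0.43, adjusted p = 0.012) and lung (-2.05, SE 0.43, adjusted p = 0.012). Il6, Tnf, Cxcl1, Saa3, S100a8 and Hmox1 did not pass at either stage (adjusted over the panel between 0.13 and 0.49). The onset total became 35 without spleen onset 1, 36 without spleen control 2, 636 without lung control 1, 3470 without lung control 2, 117 without liver control 1, 3203 without liver control 2, 374 without liver onset 1 and 3218 without liver onset 2. Without the spleen controls the late total was 71 and 70, without lung control 1 and 2 844 and 5500, without liver control 1 and 2 209 and 4578, without the spleen late arrays 70 and 71, without the lung late arrays 59 each, and without the liver late arrays 74 and 69. The directions in lung and liver rest on arrays at odds with their labels.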

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

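The test of probes without a gene name was chosen only after the values were seen, and the tests of tissue differences were set before.

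The effect of infection differed between tissues, as labelled, in 55 genes at onset and 131 late, by limma's F test on the differences between the tissues' folds. Among genes called with opposite signs in 2 tissues, those with the smallest p at onset were pancreatic. Reg2 was at least 1880-fold higher in spleen (adjusted p = 3.8e-05), Pnlip at least 709-fold (3.8e-05), Pnliprp2 at least 58.6-fold and Gm5771 at least 609-fold (6.8e-05 each), and Prss1 at least 939-fold (0.00019). In lung these 5 were not well above background on any array of either group, and in liver on at most 1 array of each group, so no fold is given there. At the late stage Klk1b3 stood at 5.53 in spleen, -1.35 in lung and -1.69 in liver, and Cela3a was 11.21 higher in spleen (adjusted p = 1.4e-05 each). Gm5771 was at least 5480-fold higher in spleen and Reg2 at least 6890-fold (1.4e-05 each), and Pnliprp2 at least 143-fold (2.2e-05). The lung and liver folds rest on control arrays that carry other tissues' markers, so the signs there cannot be read as effects of infection.

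In the panel of inflammatory genes, the late fold against control, as labelled, differed between tissues for Il1b (limma's F test, adjusted p over the panel = 0.014) and Cxcl10 (0.011). The folds were 2.77 and 3.02 in spleen, 3.81 and 2.89 in lung and 2.30 and 4.94 in liver. Adjusted over all genes the F-test p-values were 0.098 and 0.068. Il1b lay between 0.95 and 1.35 on the 6 arrays labelled control, and Cxcl10 between 2.62 and 3.48. The lung and liver folds rest on control arrays that carry other tissues' markers. These differences therefore cannot be read as effects of infection alone.

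Probes without a gene name also responded in the spleen. Of 11804 such probes tested at onset 52 rose and 7 fell, and of 11808 tested late 56 rose and 7 fell. They were not named or used in any comparison.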

How the results depend on the processing

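The fits without the 5 arrays, on the arrays of 1 slide alone and with the scan session as a random block were chosen after the data were seen. Counts are of genes called, in the order onset, late and late against onset, unless stated. The causes of the moves were not tested, except where they follow from how a setting is built. With 1 array left out, the lone array of its group is assumed to vary like the others.

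Each array left out in turn gave 65 to 71, 114 to 125 and 0 to 0 in spleen, 142 to 4545, 174 to 3722 and 12 to 19 in lung, and 551 to 4302, 241 to 6003 and 0 to 2723 in liver. Genes differing between tissues numbered 35 to 3470 at onset and 59 to 5500 late. Lists passing numbered 22 to 23 and 20 to 21 in spleen, 27 to 33 and 27 to 32 in lung, and 24 to 38 and 31 to 36 in liver.

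The fit per tissue gave 7073, 7902 and 5515 in spleen, 0 for lung late against onset, and 0, 0 and 0 in liver (1156 in lung and 1907, 3375 and 511 in liver at an unadjusted p under 0.05 in limma). Without the 5 arrays the spleen gave 7772, 8521 and 6385, lung late against onset 5941 and liver late against onset 5894.

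The strict filter, which tests fewer genes, gave 64, 133 and 0 in spleen, 492, 369 and 0 in lung and 379, 1739 and 16 in liver (279 and 215 at an unadjusted p under 0.05 in limma where 0 passed), with 3 and 4 genes differing between tissues. No filter on dim probes gave 1 for spleen late against onset, 5763 for lung onset (1310 higher, 4453 lower) and 4174 for liver onset (950 higher, 3224 lower). It also turned the balance of lung late (721 higher, 952 lower) and liver late (1857 and 2003). The strict filter did so for liver late against onset (5 and 11).

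The replicate number as a block gave 90, 170 and 0 in spleen, 367, 467 and 27 in lung and 232, 1382 and 0 in liver (581 and 1471 unadjusted in limma where 0 passed), with 67 genes differing between tissues late. Replicates that share a number correlated between -0.22 and 0.187 across groups, so the numbers gave no sign of pairing.

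The slide as a fixed term gave 701, 3021 and 2838 in spleen, 5365, 2650 and 3150 in lung, 5056 and, late against onset, 3231 in liver, 1811 and 3573 genes differing between tissues, and 32 lists in spleen late. By construction this term is estimated from the lung and liver controls, the only groups on both slides, whose arrays carry different tissues. It moved the median gene of spleen late from -0.059 to 0.404, and to 0.524, 0.391 and 0.453 in late against onset of spleen, lung and liver. It turned S100a8 to 3.58 in spleen late, 3.20 in spleen late against onset, 3.52 in lung late against onset, 1.85 in liver late and 2.33 in liver late against onset, and Blnk in liver late to 0.27. Slide 1 alone, with 1 control array for lung and for liver, gave 628, 4055 and 3683 for onset in spleen, lung and liver. Slide 2 alone, likewise with 1 control array each, gave 11351 and 11940 for late in lung and liver and turned S100a8 in liver late to 1.43. The scan session as a random block (correlation 0.531) gave 357, 100 and 0 in spleen, 118, 1809 and 15 in lung, and 79 and, late against onset, 0 in liver (273 and 632 unadjusted in limma where 0 passed).

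Normexp background correction gave 4667 and 3456 in lung onset and late and 2346 in liver onset. It moved the share of calls that were higher from 82.2% to 67.7% in spleen late and from 60% to 80% in spleen late against onset, and the median gene of liver late against onset from 0.029 to 0.175, with 18 higher and 23 lower. Quantile normalization gave 2 in spleen late against onset, 1970, 1757 and 107 in lung, 110 in liver late against onset (75 higher, 35 lower) and 356 genes differing between tissues late. The authors' values gave 0 for spleen late against onset (664 unadjusted in limma), 1458 for liver onset, 1998 higher and 2055 lower for liver late, and 14 genes differing between tissues at onset.

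Camera with an estimated correlation passed 9 and 8 lists in spleen, 2 and 3 in lung and 2 and 2 in liver, against 23, 21, 32, 27, 33 and 36 at the preset one. Fry passed 9 and 11 in spleen, 14 and 13 in lung and 16 in liver onset. The mean of probes turned Xaf1 in lung onset to -1.26 and Slc10a1 in liver late to -0.14. With the pool as a random block (correlation 0.034), a minimum of a 2-fold change or the mean of probes, all counts stayed within 1.5 times. Of 630 single gene values, calls were lost for 311 in the fit per tissue, 223 with the replicate block, 200 with the scan session, 94 with quantile normalization, 86 with normexp, 76 with the authors' values and 66 with the slide term. With each array left out in turn, counted once for each value and array, 974 calls were lost and 1502 values kept their side of the threshold.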

Other observations

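The tests of array identity, of acute phase induction in the lung and of melanocyte genes were chosen only after the results were seen.

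Il6, Adamts4 and Ccl2 separated all 12 infected arrays from all 6 arrays labelled control most widely, whichever tissue the control arrays hold. In 338 genes the lowest infected value lay above the highest control value, 71 of them by 1 log2 or more, against 0.924 expected by chance in each direction for independent arrays. The arrays are not independent, since the tissues of a stage come from the same 6 mice per the labels, so chance gives more than that by an amount not estimated here. If 2 of the control arrays repeat others, the same formula gives 9.43. The gap between the groups was 4.85 for Il6, 4.67 for Adamts4, 4.48 for Ccl2, 3.93 for Ccl3, 3.65 for Cxcl1, 3.52 for Acod1, 3.08 for Tnfaip3, 3.07 for Ccl7, 3.03 for Inhbb, 3.02 for Socs3, 3.00 for Ccl4, 2.63 for Cxcl10, 2.62 for Gbp5, 2.61 for Ms4a6d, 2.59 for Cxcl2, 2.45 for Clec4e and 2.41 for Saa3, the genes with the widest gaps. They were not tested as a set. In 104 genes every infected array lay below, 6 of them by 1 or more. Pools of 2 stages and 3 tissues are counted together here, and the late and control arrays differ in slide and session.

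Some melanocyte genes were lower in infected spleens than in control spleens, and others were not. Dct stood at 3.73 and 4.12 in the controls, -5.97 and -7.01 at onset and -4.93 and -5.22 late, and Pmel fell by 5.94 (adjusted p = 0.015) and by 5.37 (0.02). Pmel was well above background on only 1 of the 2 infected spleen arrays at each stage. At onset Tyrp1 was at least 84.1-fold lower (adjusted p = 0.2; 8.9e-06 in the spleen fit), Mlana at least 30.4-fold (0.26; 3.1e-06), Sox10 at least 5.42-fold (0.21; 0.0005) and Slc45a2 at least 2.17-fold (0.11; 0.0022). Tyr, the key enzyme of melanin synthesis, differed by -0.85 (0.87; 0.08) and the melanocyte factor Mitf by -0.08 (1; 0.76). Dct was at 3.64 and 3.71 on the arrays labelled lung control 2 and liver control 2, at 2.11 on the array labelled lung control 1 and at 1.50 on the infected array liver onset 1.

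Clock genes in the spleen were compared for the hour of collection, since control and late spleens were collected at 18 h and onset spleens at 6 h. Of 20 clock genes 6 had a larger absolute fold at onset than late (exact sign test, two-sided p = 0.12), with median absolute folds of 0.52 and 1.01. The hour cannot be separated from the stage at onset by this design, so it may still enter the onset values. The same holds for late against onset in each tissue.

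On 5 arrays the markers of the label's tissue stand low and those of another high, and lung RNA mixed in part into the sample labelled liver onset 2 is excluded, since its hepatocyte list stood at -10.76 relative to liver onset 1 (it correlated at 0.995 with lung onset 1). The hepatocyte list was 9.23 higher on the array labelled lung control 1 and the lung epithelial list 6.57 higher on the array labelled liver control 1, but these markers prompted the test, so an exchange cannot be told apart from separate wrong labels. The array labelled lung control 2 shared spot deviations with spleen control 2 at a rho of 0.7808 (at most 0.2255 with any other array), which is consistent with a second scan of the same array, whose slide number and position its header carries. For the array labelled liver control 2 and spleen control 1 the rho was 0.3735, against at most 0.2997 with the others and up to 0.5864 among the other pairs of arrays, the highest being neighbours on 1 slide scanned in 1 session, so a second scan cannot be told apart from a separate spleen sample, although its header too carries the slide and position of spleen control 1. The log ratio of lung control 2 over liver control 2 followed that of spleen control 2 over 1 at a Spearman rho of 0.7193 (-0.2917 to 0.0804 for 5 other replicate ratios), which goes with second scans, but an array shared by both ratios raises this rho by itself.

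Exocrine pancreas genes stood high in both infected spleen groups, at onset as well as late. Pancreas tissue collected with the spleen would bring islet hormones, whose median rise late was 1.1 over 7 genes. Of these 4 were higher by 1 or more, Ins1 by 3.55 (adjusted p = 4.8e-06 in the spleen fit), Iapp by 2.59, Gcg by 2.4 and Ins2 by 1.1 (0.0028), and Sst, Pyy and Ppy differed by 0.36, 0.13 and -0.11. Gcg, Iapp and Sst did not pass the filter on dim probes, yet they enter this median and this count. Of the genes that passed, Ins1 and Ins2 were higher by 1 or more, and Pyy and Ppy were not. A change of the enzyme genes within spleen cells alone would leave islet genes under 1, and the same 1.1 does not settle it, as the spread of the median is 0.85 (a rule on the spread set after the values were seen). The pancreas list differed by only 0.09 between the late pools and -0.03 between the onset pools, and neither explanation can be told apart from the other.

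Hepatocyte genes stood high in both lung late arrays and in neither lung onset array. Acute phase induction within lung cells as the whole cause is excluded, since 8 liver genes that it does not raise, Alb, Ttr, Rbp4, Apoa1, Ahsg, Serpina6, Trf and Fetub, rose by a median of 5.76 (1.47 to 9.10). Liver tissue or RNA in the samples would raise bile acid genes too, whose median rise was 1.57 over 16 genes, from -0.32 to 8.80, with 10 of them at 1 or more and a spread of 0.96, which leaves it open. The hepatocyte list in lung late stood at -3.94 relative to liver late (quartiles -4.19 and -2.83), and in lung onset at -10.83 relative to liver onset 1, and the late lung pools differed by 0.02. A biological explanation other than acute phase induction was not tested.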
